A study of Homo sapiens with 102 samples.

How the data were processed

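Gene expression was measured on arrays from human skin: 20 of normal skin, 12 of plaque psoriasis lesions, 40 of inverse psoriasis and 30 of erythrodermic psoriasis, grouped by the source named in the labels. Per the labels' protocols, RNA came from formalin-fixed, paraffin-embedded biopsy sections, was amplified to cDNA with a Nugen whole-transcriptome kit made for small and degraded RNA, and was labelled with biotin. Formalin fixation breaks and modifies RNA, so the yield of intact RNA can differ between blocks, and no measure of RNA quality was given in the sources used here. Per the submitters' processing notes, the values were made with affy and RMA, which corrects background, normalizes between arrays and summarises probes into probe sets, with no version named. The array model and the probe definitions were not given in the sources used here.

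The deposited file holds the authors' log2 expression values, a single value per probe set and array, from -1.58 to 12.07 over 25577 probe sets. Each probe set identifier is an Entrez gene number, so every gene had a single probe set. Of these, 24834 (97.1%) matched a gene symbol in the NCBI RefSeq gene list of assembly GRCh38.p14 and 743 did not. That list was used for names alone, and no coordinates are given because no genome build was stated. A second deposited file of the authors holds a log2 fold change and a q-value per probe set. The authors' log2 fold changes equalled the log2 ratio of the mean linear value of the 40 inverse arrays to that of the 20 normal arrays, within 3.97e-07. Among the tested probe sets, 4855 had a spreadsheet error in place of the deposited q-value and were counted as having none.

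XIST and Y-linked probe sets (43) were left out, which left 25534 tested. No array was left out. Arrays correlated with each other at 0.397 to 0.931 across probe sets, and no pair held identical values. The labels give no batch, date or donor. Nothing says which arrays come from separate donors, so p-values measure the spread between these arrays, which may be technical. For arrays the number in each group limits the precision, and the group of 12 gives the widest errors.

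Differences were fitted with limma 3.58.1 in R 4.3.3 (with data.table, version 1.17.8) on the deposited log2 values, with 1 mean per group, no covariate, all arrays in 1 fit and 6 contrasts. Each test was two-sided, p-values were adjusted with the Benjamini-Hochberg method over the 25534 probe sets, and a gene is said to have risen or fallen where adjusted p was under 0.05. Fold changes are differences of mean log2 values with their SE. Group values are mean ± SD unless an SE is named. On resampled arrays with 50 genes per step shifted by known amounts among 25534 tested, the fit recovered 26.0% of genes changed by 0.5 on the log2 scale, 80.0% of those changed by 1 and all 50 changed by 2 for plaque against normal skin. For inverse against normal skin it recovered 68.0%, 90.0% and 50 of 50, and for erythrodermic against normal skin 58.0%, 94.0% and 50 of 50. It made 1, 11 and 5 false calls in the same order. The arrays were drawn once, with replacement, from residuals around the group means, so array differences that go with the groups were left out. Error rates on the real arrays can be higher, as a random split of them gave up to 3949 calls.

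Gene lists were fixed before the data were examined, as were the 4 groups, the tests, the rule for named genes and most alternatives. The 31 lists hold 373 genes, of which 367 were measured. They cover the IL-17 response of keratinocytes, the IL-1 and IL-36 family, the type I interferon response, the interferon-gamma response, the TNF and NF-kappaB response, the IL-4 and IL-13 axis, the IL-23 and Th17 cytokine axis, the Th1 axis, epidermal differentiation of normal skin, inducible cornified envelope genes, hyperproliferative keratins, cell cycle genes, sebaceous and lipid synthesis genes, immediate early genes and ribosomal proteins. Cell type lists cover T cells, cytotoxic lymphocytes, neutrophils, macrophages and dendritic cells, Langerhans cells, mast cells, B and plasma cells, sweat and apocrine glands, adipocytes, smooth muscle, skeletal muscle, hair follicle, melanocytes, fibroblasts and matrix, endothelium and red blood cells.

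Each list was tested against all other genes with limma's camera at its preset inter-gene correlation of 0.01, and again with an estimated correlation, adjusting over the 186 tests of 31 lists in 6 comparisons. Beside it stands the number of members that passed over all probe sets and the number that passed when adjusted over the list alone. A list score was the mean, over the members, of the log2 value minus the mean of normal skin, and differences of scores were tested with 100000 permutations, two-sided, adjusted over 186 tests (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3). The smallest p these permutations can give is 1e-05. Scores of the 2 parts of the normal arrays were compared with exact permutation tests. Figures were drawn with matplotlib 3.10.9.

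Named genes are, per comparison, the 6 largest rises and the 6 largest falls among genes that passed, up to 3 members of each list with the largest absolute change, and 20 genes fixed in advance: IL17A, IL17F, IL22, IL23A, TNF, IFNG, IL4, IL13, IL36G, CXCL9, CXCL10, MX1, DEFB4A, S100A7, S100A9, LCN2, CCL20, CCL18, KRT16 and FLG. Near-identical genes such as SERPINB3 and SERPINB4, KRT6A, KRT6B and KRT6C, the SPRR2 genes and members of snoRNA clusters can share probes, so a value of one of them can hold signal of another.

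Alternatives were centring each array on its median, quantile normalization, leaving out probe sets of low mean value, eBayes with trend and robust, array quality weights, a fit of only the compared groups, an array deviation covariate, each numbered part of the normal arrays alone (1 to 12 and 13 to 20), the number in the titles as a block, 12 arrays drawn per group (20 draws), other thresholds, an estimated correlation and the authors' deposited table. Chosen after the data were seen were the SD of each array's log2 values as a covariate, leaving out arrays with an SD under 1, and setting plaque against normal arrays 1 to 12 with inverse and erythrodermic against 13 to 20. This pairing was assumed for the test, and no label ties a form to a part. In the order of the samples, plaque comes right after normal arrays 1 to 12, and erythrodermic and inverse come after 13 to 20. The array SD differed between groups, so this covariate can also remove part of a true difference between them. The parts of the normal arrays follow the numbers in the titles and the order of the samples, and no label calls them batches.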

Results

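Skin biopsies of 3 forms of psoriasis were set against normal skin and against each other on expression arrays. Plaque psoriasis (12 arrays) is the common form with thick scaly lesions, inverse psoriasis (40 arrays) affects skin folds, erythrodermic psoriasis (30 arrays) covers most of the body surface with inflamed skin, and 20 arrays came from normal skin. The series title asks which inflammatory signals link the 3 forms. Each array carried 25577 probe sets, 1 per gene, and 25534 were tested.

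The spread of values differed between arrays. The SD of the log2 values within an array was 1.05 ± 0.14 in normal skin (n = 20), 1.25 ± 0.16 in plaque (n = 12), 1.14 ± 0.19 in inverse (n = 40) and 1.12 ± 0.12 in erythrodermic skin (n = 30). It lay under 1 on 10 of 20 normal, 0 of 12 plaque, 11 of 40 inverse and 7 of 30 erythrodermic arrays. The first principal component held 26.0% of the variance, the second 3.11% and the third 2.00%. Arrays were ordered along the first component by their SD (Pearson r = 0.988, Spearman rho = 0.993, permutation p = 1e-05 for each, the smallest possible, and r = 0.989 without the 2 arrays farthest from the median SD). Within normal, plaque, inverse and erythrodermic arrays r was 0.985, 0.997, 0.993 and 0.993, each with permutation p = 1e-05, also after adjustment over these 5 relations.

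**Figure D1:**
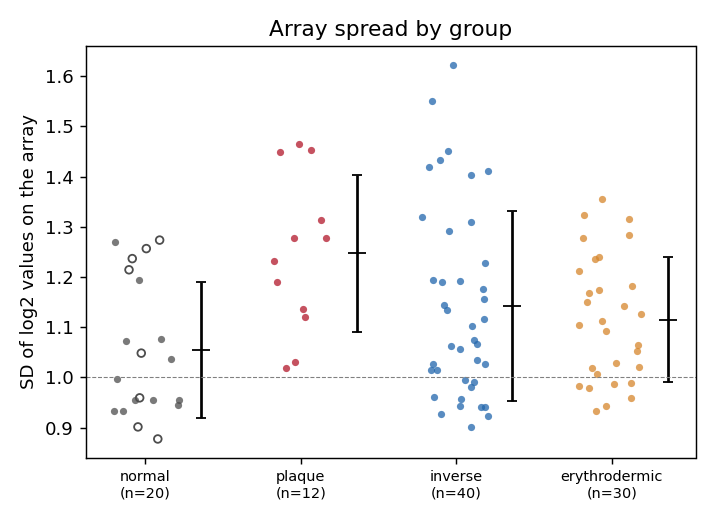
SD of the log2 values of each array (y axis, log2 units) by group (x axis): points are arrays, open circles are normal arrays 13 to 20, the black bar is mean ± SD and the dashed line marks an SD of 1. Plaque arrays have no SD under 1 and a mean of 1.25, against 1.05 in normal skin.

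The 20 normal arrays also fell into a pair of numbered parts. The score of the IL-17 response list, antimicrobial and chemokine genes that keratinocytes express under IL-17, was 0.43 ± 0.30 on normal arrays 1 to 12 and -0.64 ± 0.40 on normal arrays 13 to 20 (n = 12 and n = 8, exact permutation test, p = 1.59e-05, adjusted p = 0.000246 over 31 lists). The inducible cornified envelope list holds proteins of the keratinocyte envelope in inflammation or repair, besides cross-linking enzymes, kallikrein proteases and SERPINB protease inhibitors. It scored 0.39 ± 0.17 and -0.58 ± 0.50 (n = 12 and n = 8, exact permutation p = 1.59e-05, adjusted p = 0.000246). The comparisons with normal skin were therefore repeated against each part, and beside each comparison stand the IL-17 score, the count and the list calls that changed.

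Plaque lesions were first compared with normal skin, where genes of the activated epidermis rose most. SERPINB4, a serine protease inhibitor of squamous epithelium, rose from 3.68 ± 1.48 to 11.15 ± 0.74, by 7.47 ± 0.67 on the log2 scale (SE; 20 normal and 12 plaque arrays) or 177-fold, above the normal mean in 12 of 12 arrays (adjusted p = 1.1e-15). PI3, the elastase inhibitor elafin, rose by 6.75 ± 0.67 (adjusted p = 3.6e-13). KRT6C, a keratin of stressed epidermis, rose by 6.42 ± 0.86 (adjusted p = 4.18e-08). SPRR2B, a cornified envelope precursor, rose by 5.72 ± 0.70 (adjusted p = 1.35e-09), as with PI3 and KRT6C in 12 of 12 arrays. SERPINB3, a close relative of SERPINB4, rose by 5.67 ± 0.65 (adjusted p = 9e-11). S100A9, a subunit of the antimicrobial protein calprotectin, rose by 5.52 ± 0.46 (adjusted p = 3.25e-17), also in 12 of 12. CCL27, a keratinocyte chemokine that draws T cells to skin, fell by 2.14 ± 0.54 (SE, below the normal mean in 12 of 12 arrays, adjusted p = 0.0079). KRT77, a keratin, fell by 1.35 ± 0.25 in 12 of 12 (adjusted p = 9.35e-05). The other largest falls were FAM95C (-1.49 ± 0.46, adjusted p = 0.0335), the small nucleolar RNAs SNORD114-2 (-1.45 ± 0.41, adjusted p = 0.0195) and SNORD114-30 (-1.43 ± 0.43, adjusted p = 0.0295), and the chorionic gonadotropin gene CGB8 (-1.36 ± 0.40, adjusted p = 0.0245), in 11 or 12 of 12 arrays.

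In plaque, 16 of 23 genes of the IL-17 response list rose and none fell (median 1.96, camera adjusted p = 4.25e-32, 17 adjusted over the list alone). S100A7A rose by 5.17 ± 0.63 and DEFB4A, a beta-defensin, by 5.04 ± 0.91 in 12 of 12 arrays (adjusted p = 1.43e-09 and 8.74e-05). The score of this list was 2.41 higher than in normal skin, above the normal mean in 12 of 12 arrays (permutation adjusted p = 0.000169). S100A7, another antimicrobial S100 protein, rose by 4.82 ± 0.49 (adjusted p = 8.06e-13) and LCN2, which binds bacterial siderophores, by 3.56 ± 0.51 (adjusted p = 2.39e-07). Of 18 inducible cornified envelope genes, 16 rose (median 3.17, adjusted p = 1.68e-46, 16 adjusted over the list alone). Of 5 hyperproliferative keratins, 4 rose (median 3.45, adjusted p = 6.13e-09, 4 adjusted over the list alone). KRT16 rose by 3.52 ± 0.39 and KRT6B by 3.45 ± 0.82 (adjusted p = 2.04e-11 and 0.00441). The IL-1 and IL-36 family had 4 rises and 1 fall among 12 genes, the same counts adjusted over the list alone (median 0.49, adjusted p = 0.00145, adjusted p = 0.0557 with an estimated correlation). Its epithelial cytokine IL36G rose by 2.84 ± 0.40 (adjusted p = 1.92e-07), and the receptor antagonists IL36RN and IL1RN rose by 1.81 ± 0.32 and 1.58 ± 0.31 (adjusted p = 6.48e-05 and 0.000372), each in 12 of 12 arrays.

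Interferon-induced genes rose in plaque as well. Of 20 type I interferon response genes, 10 rose (15 adjusted over the list alone, median 0.65, adjusted p = 1.87e-12, adjusted p = 0.0495 with an estimated correlation). IFI27 rose by 1.89 ± 0.34 (adjusted p = 5.7e-05), the antiviral GTPase MX1 by 1.70 ± 0.39 (adjusted p = 0.00275) and IFI44 by 1.56 ± 0.40 (adjusted p = 0.00885). Of 20 interferon-gamma response genes, 7 rose (12 adjusted over the list alone, median 0.76, adjusted p = 8.83e-09, adjusted p = 0.0942 with an estimated correlation). Among them were GBP2 (1.55 ± 0.35, adjusted p = 0.00281) and HLA-DRA (1.48 ± 0.37, adjusted p = 0.00729). The TNF and NF-kappaB list had 5 rises among 16 (6 adjusted over the list alone, median 0.20, adjusted p = 0.00145, adjusted p = 0.112 with an estimated correlation). CCL2, a monocyte chemokine, stood at 2.07 ± 0.54, SOD2 at 2.00 ± 0.44 and NFKBIA at 1.21 ± 0.32 (adjusted p = 0.0111, 0.00168 and 0.0127). Immediate early genes, which respond within minutes to stress or growth factors, had 5 rises among 9 (6 adjusted over the list alone, median 0.56, adjusted p = 2.66e-07). They were ZFP36 (2.12 ± 0.39, adjusted p = 0.000116), JUNB (1.78 ± 0.25, adjusted p = 1.66e-07), EGR1 (1.15 ± 0.31, adjusted p = 0.0128) and 2 others. Of 20 cell cycle genes, 9 rose (12 adjusted over the list alone, median 0.53, adjusted p = 7.93e-09). Among them were TOP2A (1.12 ± 0.25, adjusted p = 0.00192), TYMS (1.10 ± 0.30, adjusted p = 0.0158) and NUSAP1 (0.89 ± 0.25, adjusted p = 0.0198).

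Cell type lists moved beside these groups in plaque. Macrophage and dendritic cell genes had 2 rises among 15, LYZ (lysozyme) at 1.97 ± 0.47 the largest (adjusted p = 0.00422), and 5 adjusted over the list alone (median 0.28, adjusted p = 0.00983, adjusted p = 0.114 with an estimated correlation). Sebaceous and lipid synthesis genes had 1 rise, HMGCS1 of cholesterol synthesis (1.70 ± 0.41, adjusted p = 0.00465), and 1 fall among 18. The list had 1 rise and 7 falls adjusted over the list alone (median -0.40, adjusted p = 0.000891, adjusted p = 0.172 with an estimated correlation). Smooth muscle genes had a median of -0.49 and none of 8 passed, also none adjusted over the list alone (adjusted p = 0.0126, adjusted p = 0.326 with an estimated correlation).

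The other plaque lists did not pass. Medians and adjusted p were -0.01 and 0.412 for the IL-4 and IL-13 axis, -0.17 and 0.125 for the IL-23 and Th17 cytokine axis, -0.10 and 0.562 for the Th1 axis, -0.01 and 0.743 for T cells, 0.09 and 0.43 for cytotoxic lymphocytes, and 0.04 and 0.919 for neutrophils. They were -0.30 and 0.286 for Langerhans cells, -0.23 and 0.093 for mast cells, -0.18 and 0.176 for B and plasma cells, 0.41 and 0.365 for epidermal differentiation of normal skin, -0.17 and 0.86 for sweat and apocrine glands, -0.02 and 0.871 for adipocytes, and -0.28 and 0.143 for skeletal muscle. They were -0.28 and 0.119 for hair follicle, 0.32 and 0.0581 for melanocytes, 0.11 and 0.583 for fibroblasts and matrix, -0.06 and 0.595 for endothelium, 0.35 and 0.597 for red blood cells, and 0.36 and 0.23 for ribosomal proteins. Within them, IL13RA1 (1.65 ± 0.38, adjusted p = 0.00271) and IL4R (1.13 ± 0.24, adjusted p = 0.00134), receptor chains for IL-4 and IL-13, rose, as did CASP14, TYRP1, AZGP1, COL6A3, GZMB and CD3D (1.68, 1.48, 1.17, 1.11, 0.90 and 0.69, adjusted p = 0.0142, 0.0408, 0.0255, 0.0427, 0.00777 and 0.0383). ACKR1, a chemokine-binding protein of venular endothelium, and HPGDS, a prostaglandin synthase of mast cells, fell by 0.80 ± 0.22 and 0.75 ± 0.25 (adjusted p = 0.0172 and 0.0498). For the IL-4 and IL-13 axis and T cells the median was negative while the mean (0.17 and 0.05) and the test's direction were positive.

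With the array SD as a covariate the rises in plaque were 13 of 23 for the IL-17 response, 16 of 18 for the cornified envelope, 3 of 20 for type I interferon, 1 of 20 for interferon-gamma, 0 of 16 for TNF, 2 of 9 for immediate early genes and 0 of 20 for the cell cycle. The macrophage list lost its call (adjusted p = 0.145). Lists that became called lower with this covariate were mast cells (median -0.55, adjusted p = 0.000476, adjusted p = 0.0271 with an estimated correlation), Langerhans cells (-0.49, adjusted p = 0.00405), fibroblasts and matrix (-0.50, adjusted p = 6.87e-07), endothelium (-0.19, adjusted p = 0.00441) and epidermal differentiation (-0.15, adjusted p = 0.0065). These last 4 did not pass with an estimated correlation (adjusted p = 0.0847, 0.0522, 0.0565 and 0.42). The cell cycle and type I interferon lists kept theirs at the preset correlation (adjusted p = 0.00035 and 2.39e-08) but lost it when this covariate was used together with the estimate (adjusted p = 0.0925 and 0.0994 with an estimated correlation).

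By limma, 1625 probe sets differed between plaque and normal skin, 1274 higher and 351 lower (78.4% higher), and 1360 of them by at least 1.5-fold. With each array centred on its median 92.8% of 1713 were higher, and quantile normalization gave 568 (72.4% higher). With the array SD as a covariate 382 passed (212 higher, 170 lower), 198 of them among the 1625, leaving out arrays with an SD under 1 gave 318, normal arrays 1 to 12 alone gave 1483 and normal arrays 13 to 20 alone 708. The IL-17 score was higher by 1.98 ± 0.27 against normal arrays 1 to 12 and 3.04 ± 0.31 (SE) against 13 to 20. Against arrays 1 to 12 the TNF, macrophage and smooth muscle lists lost their call (adjusted p = 0.0771, 0.111 and 0.311), epidermal differentiation and melanocytes were called higher (median 0.76 and 0.54, adjusted p = 0.0372 and 0.00283) and hair follicle lower (adjusted p = 0.0462). Against arrays 13 to 20 neutrophils were called higher (adjusted p = 0.0344) and Langerhans and mast cells lower (adjusted p = 0.0104 and 0.000163), and epidermal differentiation stood at -0.16 (adjusted p = 0.244). These list calls were made at the preset correlation. SERPINB4 stood at 6.40 against normal arrays 1 to 12 and 9.07 against 13 to 20 (adjusted p = 4.86e-10 and 3.89e-14), and CCL27 at -2.05 and -2.28 (adjusted p = 0.0299 and 0.0563). Against arrays 1 to 12 the calls of FAM95C, CGB8, SNORD114-2, SNORD114-30, NUSAP1, COL6A3, CD3D, ACKR1 and HPGDS ended. Against arrays 13 to 20 those of FAM95C, CGB8, MX1, IFI44, GBP2, HLA-DRA, CCL2, EGR1, HMGCS1, TYMS, NUSAP1, IL13RA1, CASP14, TYRP1, AZGP1, COL6A3, GZMB and CD3D ended besides CCL27. Calls that ended with the array SD covariate include FAM95C, SNORD114-2, SNORD114-30, CGB8, MX1, KRT6B, EGR1, CCL2, SOD2, NFKBIA, LYZ, IFI44, GBP2, HLA-DRA, HMGCS1, TOP2A, TYMS, NUSAP1, IL4R, IL13RA1, CASP14, TYRP1, AZGP1, COL6A3, GZMB and CD3D.

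Inverse psoriasis was then compared with normal skin, and the same kinds of epidermal genes led. SERPINB4 rose by 4.24 ± 0.50 (SE; 20 normal and 40 inverse arrays) or 18.9-fold, above the normal mean in 37 of 40 arrays (adjusted p = 1.34e-09). KRT6C rose by 4.03 ± 0.64 in 34 of 40 (adjusted p = 2.22e-05) and PI3 by 3.91 ± 0.50 in 37 (adjusted p = 3.37e-08). S100A9 rose by 3.13 ± 0.34 in 39 (adjusted p = 9.85e-11), SERPINB3 by 3.03 ± 0.48 in 36 (adjusted p = 2.22e-05) and S100A7A by 2.87 ± 0.47 in 36 (adjusted p = 4.28e-05). The largest falls were non-coding RNAs. The microRNA gene MIR20B fell by 1.22 ± 0.21 (SE, below the normal mean in 39 of 40 arrays, adjusted p = 7.44e-05) and PGM5-AS1 fell by 1.06 ± 0.23 (35 of 40, adjusted p = 0.00514). MIR548I2, MIR577, MIR548H1 and MIR4300 changed by -1.17, -1.12, -1.08 and -1.05 (adjusted p = 0.0184, 0.0482, 0.0475 and 0.0364). KRT77 fell by 0.89 ± 0.19 in 35 of 40 (adjusted p = 0.00336) and ACKR1 fell by 0.69 ± 0.17 in 36 (adjusted p = 0.0197).

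In inverse skin 9 of 23 IL-17 response genes rose (16 adjusted over the list alone, median 0.90, adjusted p = 2.2e-32). S100A7 rose by 2.73 ± 0.37 (adjusted p = 1.41e-07) and LCN2 by 1.65 ± 0.38 (adjusted p = 0.012). The list score was 1.31 higher, above the normal mean in 38 of 40 arrays (permutation adjusted p = 0.000169). Of 18 inducible cornified envelope genes 15 rose (16 adjusted over the list alone, median 1.66, adjusted p = 7.39e-44), with LCE3D at 2.70 ± 0.37 (adjusted p = 1.8e-07). Of 5 hyperproliferative keratins 3 rose (4 adjusted over the list alone, median 1.84, adjusted p = 2.1e-12), KRT16 by 2.40 ± 0.29 (adjusted p = 2.76e-09). The cell cycle list was higher (median 0.30, adjusted p = 8.51e-09) with 0 of 20 genes past the threshold and 3 adjusted over the list alone. JUNB was the 1 immediate early gene of 9 that rose (0.94 ± 0.19, adjusted p = 0.00193), with 4 adjusted over the list alone (median 0.33, adjusted p = 7.49e-06).

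The remaining inverse lists that passed lost their call with an estimated correlation. Median, adjusted p and adjusted p with an estimated correlation were 0.17, 0.0143 and 0.132 for the IL-1 and IL-36 family, with 4 rises and 1 fall adjusted over the list alone. In it IL36G rose by 1.37 ± 0.30 (adjusted p = 0.00688) and IL36RN by 1.07 ± 0.24 (adjusted p = 0.011). The same values were 0.36, 2.54e-08 and 0.114 for the type I interferon response (1 of 20 rose, IFI27 by 1.02 ± 0.25, adjusted p = 0.026, and 9 adjusted over the list alone). They were 0.31, 2.66e-07 and 0.123 for the interferon-gamma response (1 of 20 rose, also 1 adjusted over the list alone). They were 0.13, 0.000756 and 0.0942 for the TNF and NF-kappaB response, and 0.15, 0.0083 and 0.112 for macrophages and dendritic cells, with no member past the threshold and 2 and 1 adjusted over the list alone. Lower lists were mast cells (-0.24, 0.00177 and 0.053), sebaceous and lipid synthesis (-0.24, 8.2e-06 and 0.0665) and smooth muscle (-0.40, 1.49e-05 and 0.0665). Again no member was past the threshold, with 1, 4 and 5 falls adjusted over the list alone, besides 1 rise among the sebaceous genes.

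By limma, 167 probe sets differed between inverse and normal skin, 126 higher and 41 lower (75.4% higher), 137 of them by at least 1.5-fold. Quantile normalization gave 158 with 53.2% higher. Against normal arrays 1 to 12 alone 9 passed and against normal arrays 13 to 20 alone 551, of which 9 and 134 were among the 167. SERPINB4 was higher against either part (3.17 and 5.84, adjusted p = 0.00202 and 8.64e-09). KRT6C (2.83, adjusted p = 0.338), SERPINB3 (2.32, adjusted p = 0.19), S100A7A (2.02, adjusted p = 0.409) and IFI27 (1.11, adjusted p = 0.446) lost their call against normal arrays 1 to 12. MIR20B (adjusted p = 0.525), PGM5-AS1, MIR548I2, KRT77, ACKR1, LCN2, IL36G, IL36RN and JUNB (adjusted p = 0.702 each) and MIR577, MIR548H1 and MIR4300 (adjusted p = 0.71 each) lost theirs too, so no fall named here passed against that part. IFI27 also missed the threshold against normal arrays 13 to 20 (adjusted p = 0.252). MIR577, MIR548H1 and MIR4300 also lost their call with the array SD as a covariate (adjusted p = 0.077, 0.0613 and 0.0812). With that covariate Langerhans cells, epidermal differentiation, sweat glands, fibroblasts and endothelium became called lower (adjusted p = 0.0253, 3.89e-06, 0.00613, 1.92e-06 and 0.00324), endothelium also with an estimated correlation (adjusted p = 0.0471) and the others not (adjusted p = 0.174, 0.149, 0.181 and 0.065 with an estimated correlation). The IL-1 and IL-36 and macrophage lists lost theirs with it (adjusted p = 0.195 and 0.109), and the cell cycle and immediate early lists lost theirs with it and the estimate together (adjusted p = 0.0925 and 0.13 with an estimated correlation). The TNF, macrophage, mast cell, smooth muscle and IL-1 and IL-36 lists lost theirs against normal arrays 1 to 12 (adjusted p = 0.175, 0.182, 0.534, 0.102 and 0.175). Hair follicle was called lower and melanocytes higher against that part (adjusted p = 0.00697 and 0.000227). Against 13 to 20 neutrophils were called higher and Langerhans cells, epidermal differentiation and sweat glands lower (adjusted p = 0.00598, 0.00889, 0.000142 and 0.0173, at the preset correlation as for the first part). The IL-17 score was higher by 0.89 ± 0.22 and 1.95 ± 0.26 (SE) against the 2 parts.

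Erythrodermic psoriasis against normal skin gave a similar set of rises. SERPINB4 rose by 4.61 ± 0.53 (SE; 20 normal and 30 erythrodermic arrays) or 24.5-fold (adjusted p = 3.19e-10) and KRT6C by 4.48 ± 0.68 (adjusted p = 4.61e-06). PI3 rose by 4.33 ± 0.53 (adjusted p = 4.57e-09) and S100A9 by 3.51 ± 0.36 (adjusted p = 5.18e-12), and these 4 were above the normal mean in 30 of 30 arrays. SERPINB3 rose by 3.26 ± 0.51 in 28 of 30 (adjusted p = 1.19e-05), and S100A8, the partner of S100A9 in calprotectin, by 3.13 ± 0.31 in 30 of 30 (adjusted p = 6.99e-13). CCL27 fell by 1.88 ± 0.43 (SE, below the normal mean in 26 of 30 arrays, adjusted p = 0.0147) and MIR20B fell by 1.16 ± 0.22 in 29 (adjusted p = 0.000697). MIR548I2, MIR4300, C13orf46 and PGM5-AS1 changed by -1.20, -1.14, -0.99 and -0.95 (adjusted p = 0.0316, 0.0387, 0.0267 and 0.0366).

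In erythrodermic skin 10 of 23 IL-17 response genes rose (16 adjusted over the list alone, median 1.09, adjusted p = 2.7e-40). S100A7 rose by 2.69 ± 0.39 (adjusted p = 1.02e-06) and LCN2 by 1.69 ± 0.40 (adjusted p = 0.0237). The list score was 1.44 higher, in 30 of 30 arrays (permutation adjusted p = 0.000169). Of 18 inducible cornified envelope genes 13 rose (16 adjusted over the list alone, median 1.73, adjusted p = 2.33e-48), LCE3E by 2.99 ± 0.43 (adjusted p = 1.02e-06). Of 5 hyperproliferative keratins 3 rose (4 adjusted over the list alone, median 2.16, adjusted p = 9.53e-14), KRT16 by 2.54 ± 0.31 (adjusted p = 2.55e-09). Cell cycle genes were higher as a list (median 0.26, adjusted p = 4.61e-09) with 0 of 20 past the threshold and 4 adjusted over the list alone. Macrophage and dendritic cell genes were higher as a list (median 0.24, adjusted p = 1.33e-05). Of its 15 genes the complement gene C1QB rose, by 0.58 ± 0.14 in 27 of 30 arrays (adjusted p = 0.0334, also 1 adjusted over the list alone). Lower lists were mast cells (median -0.31, adjusted p = 0.000711, 0 of 6 past the threshold and 3 adjusted over the list alone) and sebaceous and lipid synthesis (median -0.32, adjusted p = 4.93e-09, 0 of 18 and 8 adjusted over the list alone).

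The remaining erythrodermic lists that passed lost their call with an estimated correlation. Median, adjusted p and adjusted p with an estimated correlation were 0.15, 0.00668 and 0.105 for the IL-1 and IL-36 family (IL36G rose 2.82-fold in 26 of 30 arrays, adjusted p = 0.00542, and IL36RN by 1.04 ± 0.26, adjusted p = 0.0331, with 4 rises and 1 fall adjusted over the list alone). They were 0.40, 1.21e-10 and 0.0665 for the type I interferon response (0 of 20, and 6 adjusted over the list alone). They were 0.31, 1.94e-07 and 0.12 for the interferon-gamma response (1 of 20 rose, also 1 adjusted over the list alone). They were 0.19, 7.67e-05 and 0.0529 for the TNF and NF-kappaB response (0 of 16, and 3 adjusted over the list alone). Immediate early genes stood at 0.39, 5.57e-05 and 0.0654 (1 of 9, JUNB by 0.91 ± 0.20, adjusted p = 0.00731, and 4 adjusted over the list alone). Lower lists were Langerhans cells (-0.38, 0.00754 and 0.114), epidermal differentiation of normal skin (-0.13, 0.00486 and 0.466), smooth muscle (-0.39, 0.000167 and 0.112) and hair follicle (-0.21, 0.0128 and 0.305), with 1, 5, 0 and 0 falls adjusted over the list alone. For fibroblasts and matrix and for endothelium, which did not pass, the median was 0.01 while the test's direction was negative, and for adipocytes 0.05.

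By limma, 113 probe sets differed between erythrodermic and normal skin, 91 higher and 22 lower (80.5% higher), 107 of them by at least 1.5-fold. Against normal arrays 1 to 12 alone 12 passed and against normal arrays 13 to 20 alone 477, of which 12 and 99 were among the 113, and the array SD as a covariate and a fit of only these 2 groups gave 171 each. SERPINB4, PI3, S100A9 and KRT16 were higher against either part, with SERPINB4 at 3.55 and 6.22 (adjusted p = 0.000322 and 2.75e-09). KRT6C (3.29, adjusted p = 0.0864), SERPINB3 (2.54, adjusted p = 0.0824) and LCE3E (2.19, adjusted p = 0.0727) lost their call against normal arrays 1 to 12. CCL27 (adjusted p = 0.595) and MIR20B, MIR548I2, MIR4300, C13orf46, PGM5-AS1, C1QB, LCN2, IL36G, IL36RN and JUNB (adjusted p = 0.81 each) lost theirs too, so no fall named here passed against that part. CCL27 also missed the threshold against normal arrays 13 to 20 (adjusted p = 0.0662). Normal arrays 1 to 12 also ended the calls of the TNF, mast cell, smooth muscle, Langerhans cell, epidermal differentiation and IL-1 and IL-36 lists (adjusted p = 0.0728, 0.401, 0.23, 0.443, 0.913 and 0.121), and melanocytes were then called higher (adjusted p = 0.0228). Against 13 to 20 hair follicle lost its call (adjusted p = 0.713), while neutrophils were called higher and sweat glands lower (adjusted p = 0.000163 and 0.0171, at the preset correlation as for the first part). The IL-17 score was higher by 1.01 ± 0.23 and 2.08 ± 0.27 (SE) against the 2 parts. The hair follicle list lost its call with the array SD as a covariate (adjusted p = 0.0541), while neutrophils were then called higher and sweat glands and fibroblasts lower (adjusted p = 0.00911, 0.00935 and 0.0054, and 0.0925, 0.214 and 0.315 with an estimated correlation).

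**Figure D2:**
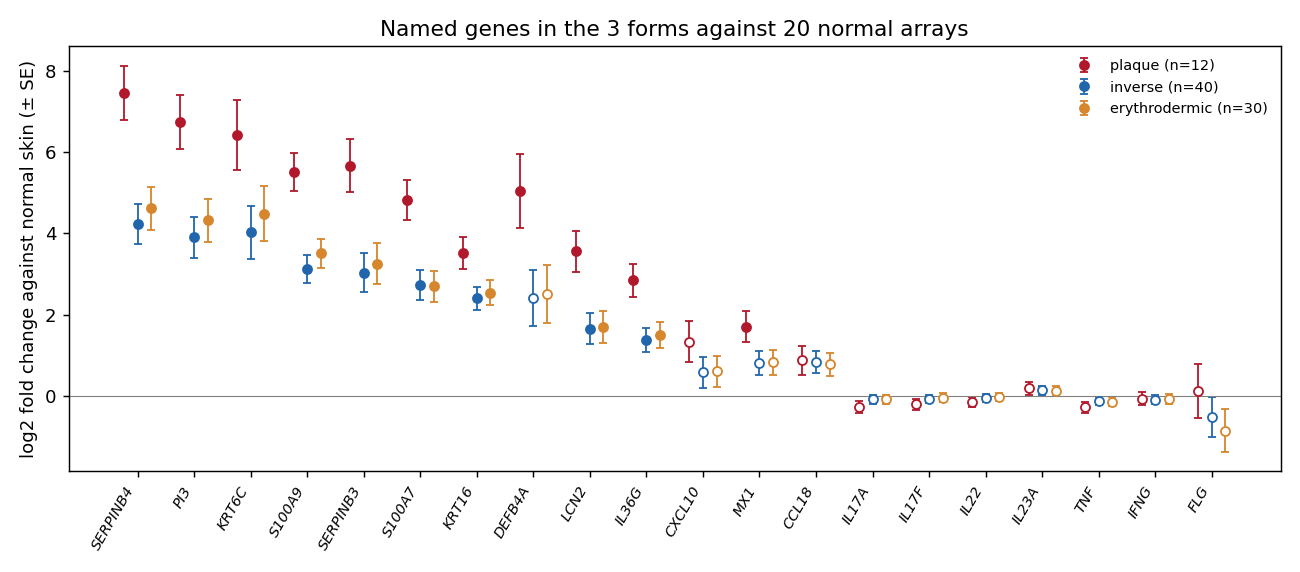
Log2 fold change ± SE (y axis) of 20 named genes (x axis) in plaque, inverse and erythrodermic skin against 20 normal arrays, with filled points where adjusted p was under 0.05 and open points where it was not. SERPINB4 stands at 7.47, 4.24 and 4.61 in the 3 forms.

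Cytokines at the top of these pathways did not pass in any form. IL17A, the cytokine that drives the keratinocyte list, differed from normal skin by -0.27 ± 0.15 in plaque, -0.09 ± 0.11 in inverse and -0.09 ± 0.12 in erythrodermic skin (adjusted p = 0.264, 0.854 and 0.907). IL17F differed by -0.21, -0.09 and -0.05, IL22 by -0.16, -0.06 and -0.03, and IL23A by 0.18, 0.13 and 0.11. TNF differed by -0.29, -0.13 and -0.14, IFNG by -0.07, -0.09 and -0.09, IL4 by -0.22, -0.10 and -0.15, and IL13 by -0.39, -0.11 and -0.20. The means of IL4, IL22, IL13, IFNG and IL17A over all arrays lay at percentiles 5.60, 7.19, 14.3, 18.2 and 23.8 of all probe sets, so these 5 hold little signal above the lowest probe sets. Those of IL23A, IL17F and TNF lay at percentiles 30.2, 50.1 and 73.4. Group means of IL23A (0.86 to 1.04) and IL17F (1.14 to 1.36) lay near or below the mean array median of 1.27. The lack of a call for these genes thus says little as well. CXCL9 and CXCL10, T cell chemokines induced by interferon-gamma, stood at 1.34 ± 0.55 and 1.33 ± 0.50 in plaque, 0.68 ± 0.41 and 0.57 ± 0.37 in inverse, and 0.58 ± 0.43 and 0.60 ± 0.39 in erythrodermic skin. CCL20 differed by 0.06, -0.08 and 0.14, CCL18 by 0.87, 0.84 and 0.77, and FLG, the barrier protein filaggrin, by 0.12 ± 0.66, -0.53 ± 0.50 and -0.86 ± 0.52. None of these genes passed in any form. DEFB4A and MX1 passed in plaque and not in inverse (2.40 ± 0.69 and 0.80 ± 0.29, adjusted p = 0.0752 and 0.221) or erythrodermic skin (2.51 ± 0.72 and 0.82 ± 0.31, adjusted p = 0.0978 and 0.309), and no difference between forms is shown by that.

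The 3 forms shared many calls against the same normal arrays. Plaque and inverse shared 120 rises and 36 falls, where independent lists would share 6.29 and 0.564. Plaque and erythrodermic shared 88 and 19 (4.54 and 0.302), and inverse and erythrodermic 79 and 13 (0.449 and 0.0353). All 3 forms shared 77 rises and 12 falls, 0 calls had opposite directions in any pair, and 8 were called in inverse alone, 3 in erythrodermic alone and 1451 in plaque alone. A call in 1 form alone shows no difference between forms. Direct comparison with plaque gave 10 calls for inverse and 0 for erythrodermic skin. Simulated unchanged groups against the same normal arrays shared at most 0, 0 and 6 calls over 20 draws. Unchanged groups give few calls to share, so these counts cannot show how much overlap shared normal arrays add to true changes. Fold changes correlated across probe sets, which are not independent replicates, at 0.903, 0.884 and 0.942, against 0.533, 0.525 and 0.606 in the simulation (highest 0.767, 0.742 and 0.821). Their covariance was 0.0926, 0.0902 and 0.0522, against 0.0178, 0.0171 and 0.0174 in the simulation, a difference of 0.0749, 0.0731 and 0.0349. With the normal arrays split in 2 sets of 10, 1 per comparison, the median of shared calls over 20 draws was 21.5, 21 and 16, and the correlations fell to 0.649, 0.636 and 0.502 (lowest 0.190, 0.156 and 0.116). Each comparison then had fewer normal arrays, which also lowers calls and precision, so the drop cannot be put down to shared normal arrays alone.

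Inverse psoriasis was next compared directly with plaque. By limma 10 genes differed, all lower in inverse skin (1395 at unadjusted p under 0.05). Chance alone puts on average 0.05 of the 25534 tests under that level, here and in the comparisons below. A fit of only these 2 groups kept 2 of the 10 and called no other, array quality weights gave 48, and 5 of 100 splits of the arrays, the real one included, gave as many calls. SERPINB4 fell by 3.23 ± 0.60 (SE; 12 plaque and 40 inverse arrays), below the plaque mean in 39 of 40 arrays (adjusted p = 0.00379). SPRR2B fell by 3.11 ± 0.63 in 35 (adjusted p = 0.013) and PI3 fell by 2.84 ± 0.61 in 38 (adjusted p = 0.0235). SERPINB3 fell by 2.64 ± 0.58 in 36 (adjusted p = 0.039) and LCE3E, a late cornified envelope gene, fell by 2.53 ± 0.49 in 36 (adjusted p = 0.00634). S100A9 fell by 2.38 ± 0.41 in 40 of 40 (adjusted p = 0.00133), and S100A7 fell by 2.10 ± 0.44 in 36 (adjusted p = 0.0235). SPRR2G, LCE3D and S100A8, named after their values were seen, changed by -2.15 ± 0.41, -2.08 ± 0.44 and -2.003 ± 0.35 in 37, 37 and 39 of 40 (adjusted p = 0.00437, 0.0235 and 0.00133). With the array SD as a covariate S100A9, S100A8, SPRR2G, SERPINB4, SPRR2B and LCE3E stayed called. With plaque set against normal arrays 1 to 12 and inverse against 13 to 20, a pairing that no label gives, none of the 10 passed, SERPINB4 standing at -0.56 ± 0.98 (adjusted p = 0.781).

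Of the lists, 10 were lower in inverse than in plaque skin and none higher. The IL-17 response list had 4 falls among 23 (15 adjusted over the list alone, median -0.93, adjusted p = 1.85e-23) and a score lower by -1.10, below the plaque mean in 36 of 40 arrays (permutation adjusted p = 0.000438). Inducible cornified envelope genes had 6 falls among 18 (16 adjusted over the list alone, median -1.60, adjusted p = 2.5e-37). Immediate early genes had 0 of 9 (3 adjusted over the list alone, median -0.40, adjusted p = 3.45e-06), ZFP36 at -1.29 ± 0.35 (adjusted p = 0.271). Median, adjusted p and adjusted p with an estimated correlation were -0.22, 0.00136 and 0.0557 for the IL-1 and IL-36 family, -0.45, 6.62e-12 and 0.0542 for the type I interferon response, -0.42, 8.4e-07 and 0.143 for the interferon-gamma response and -0.08, 0.0332 and 0.305 for the TNF and NF-kappaB response. They were -0.42, 0.00117 and 0.406 for epidermal differentiation, -1.12, 0.00039 and 0.0557 for hyperproliferative keratins and -0.24, 1.23e-05 and 0.102 for cell cycle genes. No member of these 7 lists passed, and 3, 7, 2, 0, 1, 2 and 0 fell adjusted over the list alone. The TNF and epidermal differentiation lists lost their call with the array SD as a covariate (adjusted p = 0.339 and 0.713), and Langerhans cells, sebaceous genes, smooth muscle and fibroblasts were called higher (adjusted p = 0.0146, 0.029, 0.0286 and 0.00137, and 0.133, 0.42, 0.387 and 0.22 with an estimated correlation). Under the same assumed pairing the IL-17 list score differed by -0.03 ± 0.37 (SE).

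Erythrodermic against plaque skin gave 0 probe sets by limma (1459 at unadjusted p under 0.05, smallest adjusted p = 0.0663), but 18 in a fit of only these 2 groups and 19 with array quality weights, while 10 lists were lower in erythrodermic skin. S100A7, SPRR2B and SERPINB4 stood at -2.13 ± 0.46, -3.03 ± 0.65 and -2.85 ± 0.62 (SE; 12 plaque and 30 erythrodermic arrays, adjusted p = 0.0663 for each). The IL-17 response list had 0 of 23 past the threshold (13 falls adjusted over the list alone, median -0.85, adjusted p = 7.87e-17) and a score lower by -0.97, below the plaque mean in 27 of 30 arrays (permutation adjusted p = 0.00118). Inducible cornified envelope genes (median -1.45, adjusted p = 5.73e-32, 16 falls adjusted over the list alone) and immediate early genes (median -0.50, adjusted p = 7.08e-07, 4 falls adjusted over the list alone) were also lower. Median, adjusted p and adjusted p with an estimated correlation were -0.28, 0.00412 and 0.0905 for the IL-1 and IL-36 family, -0.37, 5.51e-09 and 0.102 for the type I interferon response, -0.41, 2.33e-06 and 0.167 for the interferon-gamma response and -0.62, 7.06e-06 and 0.225 for epidermal differentiation. They were -0.99, 0.00226 and 0.105 for hyperproliferative keratins, -0.22, 3.45e-05 and 0.114 for cell cycle genes and -0.40, 0.00132 and 0.129 for melanocytes, with 1, 0, 2, 3, 2, 0 and 0 falls adjusted over the list alone in these 7 lists. The IL-1 and IL-36, interferon-gamma, epidermal differentiation, cell cycle and melanocyte lists lost their call with the array SD as a covariate (adjusted p = 0.193, 0.54, 0.37, 0.474 and 0.32), and smooth muscle, fibroblasts and endothelium were called higher (adjusted p = 0.00179, 8.75e-08 and 0.00613, and 0.181, 0.0331 and 0.0682 with an estimated correlation). Immediate early genes kept their call with it but not with it and the estimate together (adjusted p = 0.0847 with an estimated correlation). With plaque against normal arrays 1 to 12 and erythrodermic against 13 to 20, again an assumed pairing, the IL-17 list score differed by 0.09 ± 0.32 (SE) and 15 probe sets passed.

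**Figure D3:**
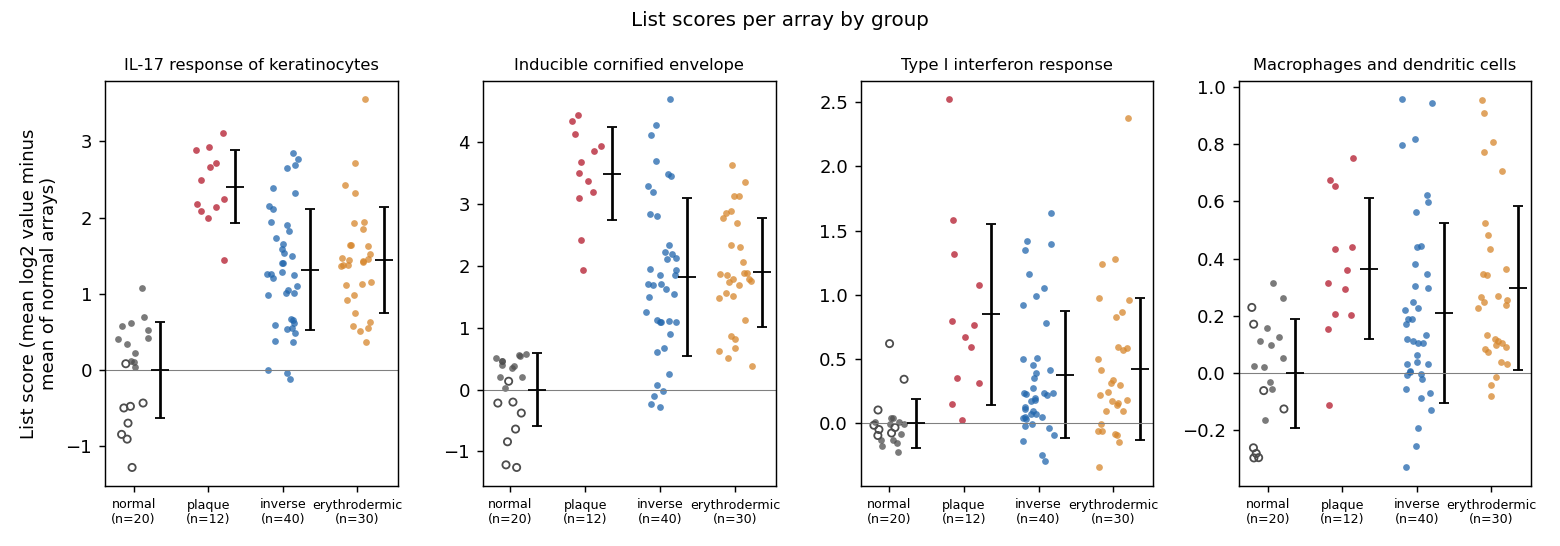
Scores (y axis, mean log2 difference from normal skin) of 4 gene lists by group (x axis): points are arrays, filled grey normal arrays 1 to 12 and open circles normal arrays 13 to 20, and the black bar is mean ± SD. The IL-17 response score is 2.41 ± 0.48 in plaque, 1.31 ± 0.80 in inverse and 1.44 ± 0.70 in erythrodermic skin.

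Erythrodermic and inverse skin differed least. By limma 0 probe sets differed (24 at unadjusted p under 0.05, smallest adjusted p = 1.00), with SERPINB4 at 0.38 ± 0.44, PI3 at 0.42 ± 0.44 and S100A9 at 0.38 ± 0.30 (SE; 40 inverse and 30 erythrodermic arrays). The count of 24 lies below the 0.05 of 25534 tests that chance gives on average, as can happen with correlated probe sets. It is thus no measure of likeness between these forms. Cell type lists moved by small amounts. Neutrophil genes were higher in erythrodermic skin (median 0.13, adjusted p = 0.000331, adjusted p = 0.0424 with an estimated correlation), as were macrophage and dendritic cell genes (median 0.09, adjusted p = 0.000164, adjusted p = 0.0275 with an estimated correlation), with C1QB at 0.26 ± 0.12 and MRC1 at 0.25 ± 0.18. Median, adjusted p and adjusted p with an estimated correlation were 0.11, 0.00177 and 0.37 for the IL-17 response, -0.26, 0.001 and 0.0557 for Langerhans cells, -0.20, 0.00108 and 0.406 for epidermal differentiation, -0.06, 0.00226 and 0.232 for sebaceous and lipid synthesis and -0.20, 0.0011 and 0.123 for melanocytes. No member of these 7 lists passed, also none adjusted over the list alone. By permutation of list scores the neutrophil and macrophage lists did not pass, with differences of 0.11 and 0.09, above the inverse mean in 20 and 17 of 30 arrays (adjusted p = 0.251 and 0.42). Without arrays of SD under 1 the macrophage list lost its call (adjusted p = 0.235) and the IL-17 median was -0.03. The epidermal differentiation and melanocyte lists lost theirs with the array SD as a covariate (adjusted p = 0.397 and 0.111), and neutrophils with it and the estimate together (adjusted p = 0.124 with an estimated correlation). The type I interferon, interferon-gamma, cornified envelope, fibroblast and endothelium lists were then called higher (adjusted p = 0.00376, 0.041, 2.65e-05, 6.02e-05 and 0.0281) and hair follicle lower (adjusted p = 0.034). None of these 6 passed with an estimated correlation (adjusted p = 0.42, 0.464, 0.16, 0.117, 0.133 and 0.369).

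Over the 6 comparisons 68 of 186 list tests passed, and 26 did with an estimated correlation. These were the IL-17 response and the inducible cornified envelope in all 3 forms against normal skin and in inverse and erythrodermic against plaque, hyperproliferative keratins and the cell cycle in all 3 forms, the type I interferon response in plaque, immediate early genes in plaque, inverse and both comparisons with plaque. They were also macrophages, mast cells and sebaceous genes in erythrodermic skin, and neutrophils and macrophages in erythrodermic against inverse skin. Of 20 lists called in the comparisons with plaque, 9 kept direction and call with plaque against normal arrays 1 to 12 and the other form against 13 to 20, at the preset correlation. None of the 9 passed there with an estimated correlation (adjusted p = 0.208 to 0.603).

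The authors' deposited table gave a q-value under 0.05 to 408 probe sets for inverse against normal skin, 403 higher and 5 lower. Of the 167 probe sets that passed in the limma fit, 131 were among them in the authors' deposited table, all with the same sign, and the fold changes correlated at 0.958 across probe sets. DEFB4A, CCL18 and MX1 had q-values of 0.00369, 0.0178 and 0.0326 in the authors' deposited table and did not pass in the limma fit.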

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

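Each result here was singled out because a test of the difference between 2 forms of psoriasis passed, with the forms otherwise compared against the same normal skin. Of the tests, these were chosen only after the result was seen: the array SD as a covariate, the ratios of counts with 12 arrays per group or against each part of the normal arrays, plaque set against normal arrays 1 to 12 with the other forms against 13 to 20, a pairing that no label gives.

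Genes that differed were all lower in inverse than in plaque skin (12 plaque and 40 inverse arrays). Log2 differences were -3.23 for SERPINB4, -3.11 for SPRR2B, -2.84 for PI3, -2.64 for SERPINB3, -2.53 for LCE3E, -2.38 for S100A9, -2.15 for SPRR2G, -2.10 for S100A7, -2.08 for LCE3D and -2.003 for S100A8. Each lay below the plaque mean in 35 to 40 of 40 arrays. Adjusted p ran from 0.00133 for S100A8 and S100A9 to 0.039 for SERPINB3, and a fit of only the 2 groups compared kept 2 of the 10.

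List scores differed by permutation as well. Inverse skin scored lower than plaque by -1.10 for the IL-17 response (36 of 40 arrays below the plaque mean, adjusted p = 0.000438), -1.67 for the inducible cornified envelope (36 of 40, adjusted p = 0.000886) and -0.47 for immediate early genes (34 of 40, adjusted p = 0.0353). The type I interferon response differed by -0.47 (32 of 40, adjusted p = 0.0443) and the IL-1 and IL-36 family by -0.35 (33 of 40, adjusted p = 0.0452). Erythrodermic skin scored lower than plaque by -0.97 for the IL-17 response (27 of 30, adjusted p = 0.00118), -1.59 for the inducible cornified envelope (29 of 30, adjusted p = 0.000169) and -0.92 for hyperproliferative keratins (29 of 30, adjusted p = 0.00697). Immediate early genes differed by -0.50 (26 of 30, adjusted p = 0.0173), melanocyte genes by -0.53 (25 of 30, adjusted p = 0.0443) and the IL-1 and IL-36 family by -0.34 (25 of 30, adjusted p = 0.0468). The keratin difference of erythrodermic skin was -0.45 ± 0.36 (SE) with the array SD as a covariate, and by camera that list had adjusted p = 0.105 with an estimated correlation. The melanocyte and IL-1 and IL-36 lists in erythrodermic skin (adjusted p = 0.129 and 0.0905) and the type I interferon and IL-1 and IL-36 lists in inverse skin (adjusted p = 0.0542 and 0.0557) did not pass with an estimated correlation either. At the preset correlation with the array SD as a covariate the 2 erythrodermic lists lost their call too (adjusted p = 0.32 and 0.193). Under the pairing that no label gives, keratins differed by 0.42 ± 0.47 (SE) and the cornified envelope by -0.63 ± 0.41, or -0.71 ± 0.58 in inverse skin. The type I interferon score of inverse skin stayed over 2 SE below 0 there (-0.63 ± 0.27), though not with the array SD as a covariate as well (-0.37 ± 0.23).

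The first pattern weighed is the larger number of changes against normal skin in plaque (1625) than in inverse (167) or erythrodermic skin (113). A difference in group size argues the other way, since with 12 arrays drawn per group the median plaque count was 44.2 times the larger of the others, and over 1.5 times in 19 of 20 single draws (lowest ratio 1.21; plaque 409 to 3860, inverse 0 to 833, erythrodermic 9 to 92). With the array SD as a covariate the counts were 382, 213 and 171, and without arrays of SD under 1 they were 318, 182 and 104. A difference in array spread may thus account for much of the gap. As the whole cause it is argued against by ratios of 1.79 with the array SD as a covariate and 6.36 with 12 arrays drawn per group as well (2.62 to 10.8 in single draws). The limit of 1.5 for these ratios was set after the data were seen, and 1.79 lies little above it. The choice of normal arrays may account for the size of the gap, since the ratio was 1.28 against normal arrays 13 to 20 and 124 against normal arrays 1 to 12. Differences in RNA quality between fixed blocks, differences in body site and a biological difference between the forms all stay open, untested. Inverse psoriasis affects skin folds, and body site entered no fit.

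The second pattern is the lower IL-17 response score in inverse and erythrodermic than in plaque skin. With the array SD as a covariate the differences were -0.85 ± 0.20 and -0.65 ± 0.21 (SE), over 2 SE below 0, which argues against array spread as the whole cause. A shift of all genes shared with the parts of the normal arrays would raise the correlation across the 25167 probe sets outside the lists, and is argued against by -0.18 with the array SD as a covariate (highest other of 100 splits 0.132, all 100 as high) and by -0.48 without it (highest other 0.628, 92 as high), though only the first lies outside the spread of splits. A shift of the list genes along with those parts cannot be told apart: under the assumed pairing the differences were -0.033 ± 0.37 and 0.094 ± 0.32 (SE), which restates the difference of -1.06 between the parts that prompted the test. RNA quality, body site and a biological difference between the forms stay open, untested.

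Other splits of the same arrays were counted with 100 splits each, the real one included. For plaque against normal skin 1 split gave as many calls (1625, highest other 13), for inverse 1 (167, highest other 47) and for erythrodermic 1 (113, highest other 42), so no other split reached the real count there. Splits treat the arrays as independent, which no label states, so chance is made unlikely and not excluded. For inverse against plaque 5 splits gave as many (10 calls, highest other 703), so chance cannot be excluded. For erythrodermic against plaque (0 calls, highest other 2) and against inverse (0 calls, highest other 3949) all 100 did, as any split must against a count of 0, so this tests nothing. For normal arrays 13 to 20 against 1 to 12, 2 splits gave as many (36 calls, highest other 725), so chance is made less likely and is not excluded. Single splits with 703, 3949 and 725 calls, far above the real 10, 0 and 36, point to a structure of the samples other than their group.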

How the results depend on the processing

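Chosen after the data were seen were the array SD covariate, leaving out arrays with an SD under 1, and plaque against normal arrays 1 to 12 with the other forms against 13 to 20 (assumed pairing). Called list results kept direction and side of the threshold in 682 of 782 values under the alternatives, 95 lost the call and 5 reversed. Named genes that passed did so in 886 of 1105 values, 219 lost the call and 0 reversed. Of lists that did not pass, 1057 of 1326 values stayed, 96 passed, 12 reversed and 161 moved, and of genes that did not pass, 5316 of 5783 stayed, 195 passed and 272 moved. Plaque counts that stayed within 1.5 times ran from 1360 (fold of at least 1.5) to 2307 (array quality weights), and erythrodermic against inverse gave 0 by limma in each setting run (24 at unadjusted p under 0.05 in the fit of all arrays). Low signal limits genes near the bottom of the arrays, such as IL22 and IL4. The mean of all probe sets of a gene was not run, since each gene had 1.

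Counts of changed probe sets moved as follows, and the cause was not tested unless given. Quantile normalization gave 568 for plaque against normal skin, 6 for inverse against plaque and 1 for erythrodermic against plaque. Normal arrays 1 to 12 alone gave 9 for inverse and 12 for erythrodermic, and 13 to 20 alone gave 708, 551 and 477 for plaque, inverse and erythrodermic. The array SD covariate gave 382 for plaque and 171 for erythrodermic, and leaving out arrays with an SD under 1 gave 318 for plaque, 6 for inverse against plaque and 5 for erythrodermic against plaque. Only the compared groups gave 171 for erythrodermic against normal skin, 2 for inverse against plaque and 18 for erythrodermic against plaque. Array quality weights gave 48 and 19 for inverse and erythrodermic against plaque, the assumed pairing with the parts of the normal arrays 16 and 15, and leaving out probe sets with a mean below the median 6 for erythrodermic against plaque. With fewer arrays, 12 drawn per group, medians were 995, 16 and 22.5 for plaque, inverse and erythrodermic and 6 for inverse against plaque. Stricter thresholds leave fewer by construction: a fold of at least 2 left 721, 82 and 73, and adjusted p under 0.01 left 507, 61 and 39, with 5 for inverse against plaque. An estimated correlation left 26 of 68 list calls. With the normal arrays split in 2 sets of 10, shared calls were 21.5 for plaque and inverse, 21 for plaque and erythrodermic and 16 for inverse and erythrodermic.

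With the array number as a replicate block, counts were 3336, 64 and 58 for plaque, inverse and erythrodermic against normal skin, and 2989 and 2328 for inverse and erythrodermic against plaque. Arrays correlated best with their own number in 1 of 12, 2 of 20, 2 of 20, 1 of 12, 1 of 12 and 0 of 30 cases over the 6 comparisons, so the numbers do not pair the arrays. That check cannot show whether values change along the numbers within a form. The IL-17 score was 2.11 to 2.85 on inverse arrays 21 to 26. Elsewhere in inverse skin it was as high only on arrays 1 and 38 (2.65 and 2.77). This run was seen afterwards and was not tested.

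List medians reversed as follows, with the cause not tested. In plaque against normal skin, epidermal differentiation was -0.15 with the array SD covariate and -0.30 without arrays of SD under 1, and fibroblasts and matrix -0.50 and -0.47. Under the assumed pairing with the parts of the normal arrays, inverse against plaque gave 0.20 for the TNF and NF-kappaB response, -0.51 for mast cells, 0.24 for hyperproliferative keratins and -0.56 for smooth muscle, and erythrodermic against plaque gave 0.020 for the IL-17 response, 0.38 for keratins and -0.47 for smooth muscle. Fibroblasts and matrix were 0.20 for inverse against plaque with the SD covariate, and for erythrodermic against plaque 0.15 with quantile normalization and 0.37 with the SD covariate. In erythrodermic against inverse without arrays of SD under 1, medians were -0.027 for the IL-17 response, -0.22 for the cornified envelope and -0.25 for keratins.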

Other observations

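Of the tests here, the biotype counts, the snoRNA set test, the snoRNA score, its difference against normal arrays 1 to 12 without a covariate, and the array SD as a covariate were chosen only after the result was seen. Small nucleolar RNAs (snoRNAs), which guide chemical modification of ribosomal RNA, made up 1.23% of the probe sets tested (313 of 25534). They made up 28 of 1274 rises in plaque (2.20%, Fisher's test, adjusted p = 0.00758), 20 of 126 in inverse (15.9%, adjusted p = 5.06e-16) and 12 of 91 in erythrodermic skin (13.2%, adjusted p = 6.38e-09). With the array SD as a covariate they were 32 of 212 (15.1%), 43 of 115 (37.4%) and 35 of 124 (28.2%; adjusted p = 1.55e-24, 2.14e-51 and 7.24e-37). Fisher's test treats probe sets as independent, here and for the other kinds of RNA below. Its p-values are too small where probe sets move together, as snoRNAs of a cluster can. Without the covariate, 8 rose in all 3 forms, and these 8 are not shown to be independent of each other. SNORD34 rose by 1.60, 1.51 and 1.45 on the log2 scale in plaque, inverse and erythrodermic skin (adjusted p = 0.0246, 0.0135 and 0.0411) and SNORD79 by 1.27, 1.21 and 1.22 (adjusted p = 0.00155, 8.89e-05 and 0.000232). SNORD29 rose by 1.43, 1.09 and 1.17 (adjusted p = 0.000224, 0.000606 and 0.000429) and SNORD47 by 1.60, 1.34 and 1.27 (adjusted p = 0.00103, 0.000606 and 0.00482), beside SNORD28, SNORD57, SNORD110 and SNORD3C. The mean over all 313 was higher than in normal skin by 0.24 ± 0.09, 0.29 ± 0.07 and 0.29 ± 0.07 (SE; above the normal mean in 12 of 12, 36 of 40 and 26 of 30 arrays, permutation p = 0.0136, 0.00014 and 0.00075). As a set against all other genes, snoRNAs passed by camera in plaque at the preset correlation (median 0.11, p = 0.00052) and not with an estimated one (p = 0.164), while inverse and erythrodermic skin gave p = 0.00367 and 0.00304 with an estimated correlation. With the covariate and the estimate together the 3 forms gave p = 0.000658, 9.07e-06 and 1.51e-05.

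MicroRNA genes, 1082 of the probe sets tested (4.24%), made up 24 of 351 falls in plaque (adjusted p = 0.0346), 7 of 41 in inverse (adjusted p = 0.00367) and 5 of 22 in erythrodermic skin (adjusted p = 0.00439). With that covariate they were 1 of 170, a smaller share than among all tested (0.588%, Fisher's test, adjusted p = 0.0203). In inverse and erythrodermic skin they were then 4 of 98 and 4 of 47, and neither share passed. Without the covariate microRNA genes made up 3 of 1274 rises in plaque, 0 of 126 in inverse and 0 of 91 in erythrodermic skin (Fisher's test, adjusted p = 1.16e-19, 0.0138 and 0.0514). With it the plaque share of rises did not pass (7 of 212, adjusted p = 0.756). Long non-coding RNAs, 3914 of the probe sets tested (15.3%), made up a larger share of falls in plaque (84 of 351, 23.9%, Fisher's test, adjusted p = 9.23e-05). Their share of rises in plaque was smaller (32 of 1274, 2.51%, adjusted p = 1.06e-52). With the covariate their share of falls in plaque was smaller too (6 of 170, 3.53%, adjusted p = 4.64e-06). They made up 7 of 41 falls in inverse and 3 of 22 in erythrodermic skin, and neither share passed (adjusted p = 0.802 for inverse). Their share of rises was smaller in these forms too (6 of 126, 4.76%, and 6 of 91, 6.59%, Fisher's test, adjusted p = 0.000793 and 0.0306). With the covariate their share of falls was smaller in inverse skin (3 of 98, adjusted p = 0.000565) and did not pass in erythrodermic skin (4 of 47, adjusted p = 0.317).

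The third pattern weighed is the share of snoRNAs among the rises. Array spread as the whole cause is argued against by score differences of 0.39, 0.36 and 0.33 with the array SD as a covariate, each over 2 SE above 0. Normal arrays 13 to 20 scored -0.41 lower than 1 to 12 for snoRNAs (exact permutation p = 0.000968), so low values in those arrays alone may be the source, and this cannot be told apart. Against normal arrays 1 to 12 the differences were 0.23, 0.21 and 0.19 with the array SD as a covariate, over 2 SE above 0. The rule for that test was written before it was run, but its score and covariate were chosen after the snoRNA pattern was seen. Without the covariate the differences were 0.077 ± 0.09, 0.13 ± 0.08 and 0.12 ± 0.08 (SE), within 2 SE of 0, so that test rests on a covariate that itself differs between groups. RNA quality in fixed tissue, body site and a biological difference from normal skin stay open, untested.

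Normal arrays 13 to 20 also differed from 1 to 12 in genes, with 36 probe sets past the threshold in a fit of the 20 normal arrays alone. In a fit with all groups 14 were higher and 0 lower, and 67 and 13 with the array SD as a covariate. Among the 14 was CCDST (1.00 ± 0.21, SE, adjusted p = 0.0376). Mast cell and melanocyte scores were higher in normal arrays 13 to 20 by 0.54 and 0.78 (exact permutation, adjusted p = 0.0183 and 0.0163). Besides the IL-17 response, cornified envelope and snoRNA scores, those of neutrophils (-0.50), the TNF and NF-kappaB response (-0.32), the IL-1 and IL-36 family (-0.25), hyperproliferative keratins (-1.34) and the cell cycle (-0.14) were lower there (exact permutation, adjusted p = 0.00131, 0.00178, 0.0201, 0.0288 and 0.0499). By camera the IL-1 and IL-36 and cell cycle lists did not pass (adjusted p = 0.247 and 0.243), and none of the 31 lists did with an estimated correlation (smallest adjusted p = 0.0864, with 0.128 for the IL-17 response, 0.504 for the cornified envelope and 0.218 for keratins). With the array SD as a covariate and the estimate together, the IL-17 response and the cornified envelope (adjusted p = 0.0106 each) and neutrophils (adjusted p = 0.0364) passed as lower. Mast cells then passed as higher (adjusted p = 0.0456).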
